A study of Mus musculus with 10 samples.

How the data were processed

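Total RNA was measured in 10 pools of medial ganglionic eminence (MGE), the ventral forebrain region that produces cortical interneurons, from mouse embryos at embryonic day 13.5. Each pool held 4 MGE, per the labels. Of the 10 pools, 5 were wildtype and 5 carried the Evf2TS/TS allele, which lacks the long non-coding RNA Evf2. The labels gave the sex of each pool: 3 wildtype pools were female and 2 male, and 2 mutant pools were female and 3 male. All pools came from a mixed strain background of 129Sv, Bl6 and Fvbn, per the labels. Nothing in the labels ties a pool number in one genotype to the same number in the other. The pools are separate samples, and p-values measure the spread between pools.

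The deposited value table holds 1 linear intensity per probe set and array, for biotin-labelled cRNA on an Affymetrix Mouse430_2 array, per the file headers and labels. It has 45101 probe sets, of which 64 are controls, and no column was left without a sample. Tested on the values, every array had the same mean signal after the top and bottom 2% of probe sets were set aside, which is the form global scaling gives. The software that summarised and scaled the arrays is not given in the sources used here. Array medians lay between 23.5 and 29.3 signal units, and 38.9% to 40.4% of probe sets reached a signal of 50. The number of arrays limits the precision.

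A second deposited table lists 96 probe sets for mutant against wildtype. Per the file headers it holds those with a corrected p of at most 0.05 in an unpaired test and a fold change of at least 2. The authors gave a ratio (absolute fold change), a log2 fold change and a linear intensity per genotype for each. Its wildtype levels were not those of the value table (median ratio 1.76), so it comes from another summary of the arrays, whose method is not given in the sources used here.

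This table was also the only source of gene names: a probe set outside it is unnamed here. Symbols were updated through Entrez numbers with RefSeq genes of GRCm38.p6, where 63 of 69 single Entrez numbers matched. Of the 96 probe sets, 64 had 1 current symbol (58 distinct genes), 10 had several symbols, 16 had none and 6 had an Entrez number without a match. Evf2 is listed by RefSeq as a synonym of Dlx6os1. The genome build of the table's alignments is not named in the file; its coordinates are given as they stand, and RefSeq served only for names and for the order of neighbouring genes.

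Intensities were tested as log2(value + 16), so fold changes are on that scale and understate changes of dim probe sets. The main fit was limma (version 3.58.1, R 4.3.3) with genotype and sex as terms, eBayes, and 2-sided p-values adjusted by Benjamini-Hochberg over 45037 probe sets; adjusted p under 0.05 was called. The sex coefficient came from the same fit. Effects within each sex and their difference came from a fit with 1 mean per genotype and sex. Values were simulated for mutant against wildtype over 45037 probe sets, with 50 changed at each fold, all with a mean signal over 50. The fit recovered 50% of 1.5-fold, 90% of 2-fold, 98% of 3-fold and 100% of 4-fold changes, with 8 false calls. The folds were set on the log2(value + 16) scale, with independent normal noise and no deviant pool. The rates therefore do not cover dim probe sets or unlike pools.

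Tests, lists and alternatives were chosen before the data were examined, apart from those named as later choices. A plan to keep 1 probe set per gene could not be carried out without names, so each probe set was tested singly. For the same reason the tests of gene lists as sets (camera and fry) and of windows on chromosome 6 were not run. Of 23 lists fixed beforehand, 18 had no named member: MGE patterning, MGE-derived interneurons, neighbouring eminences and striatum, pallium, septum and diencephalon, endothelium, microglia, erythroid cells, meninges, radial glia, sonic hedgehog, chromatin and cohesin, neurotransmitter receptors, oligodendrocyte precursors, immediate early genes, hypoxia, sex-linked genes and strain-variable genes. The genes named were the Evf2 locus and study genes, and up to 4 members of each list. The 12 largest rises and 12 largest falls past the threshold were also named, leaving out predicted transcripts and probe sets with several symbols. Where a gene had several listed and called probe sets, the brightest stood for it. Probe sets of the same gene outside the deposited list could not be identified. Alternatives changed the filter, scaling, pseudocount, variance model, weights, covariates and threshold, and left out each pool in turn.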

Results

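Gene expression was measured on 10 arrays of embryonic mouse MGE, 5 pools from wildtype embryos and 5 from Evf2TS/TS mutants. Signals of any pair of arrays correlated across probe sets with r between 0.969 and 0.989 (genes are not independent replicates). The comparison asked which transcripts differ when Evf2, an RNA transcribed across the Dlx5/6 enhancers, is lost.

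Evf2 itself was nearly lost from mutant MGE. The probe set of Dlx6os1, the gene RefSeq lists with Evf2 as a synonym, read 609 ± 177 signal units in wildtype and 22.4 ± 20.2 in mutant pools (SD, n = 5 each). Its log2 difference was -4.07 ± 0.28 (SE; limma, adjusted p = 0.00011), and every mutant pool lay below every wildtype pool. The size depended on the pseudocount (-2.95 at pseudocount 64 and -4.90 at pseudocount 1). Its neighbour Dlx6, a homeobox transcription factor of forebrain interneuron precursors, rose from 316 ± 36.4 to 737 ± 186, a log2 difference of 1.16 ± 0.17 (adjusted p = 0.0118). The Dlx6 probe set aligned to chromosome 6 at 6813796 to 6817970, in a build the table does not name. The Dlx6 call ended in 5 of 22 settings, among them pseudocount 1 (adjusted p = 0.0729) and the omission of wildtype replicate 5 (adjusted p = 0.0548) or mutant replicate 1 (adjusted p = 0.0637).

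Further genes of the chromosome 6 list also changed, in both directions. Akr1b8, an aldo-keto reductase, rose from 10.7 ± 3.10 to 84.5 ± 7.86 (log2 difference 1.94 ± 0.10, adjusted p = 1.75e-05; 1.001 at pseudocount 64 and 2.95 at pseudocount 1). Rbm28, an RNA-binding protein, rose from 142 ± 27.6 to 333 ± 79.1 (1.13 ± 0.18, adjusted p = 0.0233). Lsm8, a component of the splicing machinery, fell from 187 ± 14.4 to 37.4 ± 38.6 (-2.22 ± 0.32, adjusted p = 0.0124; -1.41 at pseudocount 64 and -2.84 at pseudocount 1). A probe set the table assigns to both Glcci1 and Gm16039, a symbol RefSeq has updated to Umad1, fell from 73.2 ± 5.80 to 28.8 ± 15.7 (-1.06 ± 0.19, adjusted p = 0.0387; -0.58 at pseudocount 64 and -1.45 at pseudocount 1), and its value belongs to neither gene singly. Counted from the start of the Dlx6 alignment, these lay 1.59 (Glcci1/Umad1), 11.99 (Lsm8), 22.3 (Rbm28) and 27.5 (Akr1b8) Mb away. The list was drawn from published work on these samples and is not independent evidence. Of its 6 members 4 were singly named, and Dlx5 had no named probe set. All 4 passed, and 4 when adjusted over the list alone. Names came only from the authors' list of changed probe sets, which nearly fixes this. Of the list of Dlx genes and GABA synthesis, Dlx6 was the 1 named member. The calls of Lsm8, Rbm28 and Glcci1/Umad1 ended in 4, 8 and 13 of 22 settings, among them pseudocount 1 (adjusted p of 0.105, 0.114 and 0.162). Without mutant replicate 1 the calls of Lsm8 (adjusted p = 0.0605), Rbm28 (adjusted p = 0.106) and Glcci1/Umad1 (adjusted p = 0.129) ended. That of Rbm28 also ended without wildtype replicate 4 or 5 or mutant replicate 2 or 3, and that of Glcci1/Umad1 without any 1 pool except mutant replicate 4 (adjusted p from 0.0684 to 0.137). The falls were not even across mutant pools. In mutant replicate 4, Lsm8 read 105 (10.4 to 28.4 in the other mutant pools) and Glcci1/Umad1 read 55.7 (17.2 to 29.4). Akr1b8 moved less, at 74.8 (79.7 to 93.8).

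**Figure D1:**
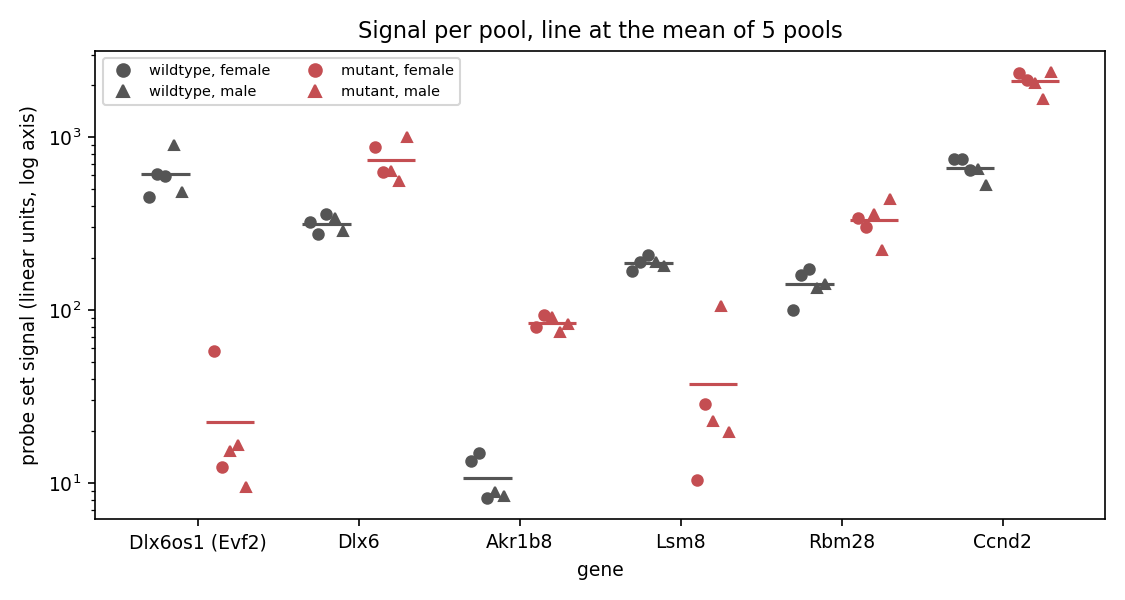
Probe set signal (linear units on a log axis) of 6 genes in each of the 10 pools; circles are female and triangles male pools, grey wildtype and red mutant, and lines mark means. Dlx6os1 (Evf2) averaged 609 in wildtype and 22.4 in mutant pools, while Dlx6 averaged 316 and 737.

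Over all probe sets, 241 of 45037 passed, 136 higher and 105 lower in the mutant, and 117 of them differed at least 2-fold. Centring each array on its median gave 243 calls with 95 higher and 148 lower, so the balance between directions depended on scaling. Groups did not overlap for 3.07% of all probe sets, against 0.794% by chance. They did not overlap for 223 of the 241, which the selection for a difference on these arrays nearly fixes. The count fell to 72 without mutant replicate 1 and to 96 without wildtype replicate 4; wildtype replicates 2 and 5 and mutant replicates 2 and 3 also moved it over 1.5 times, to 133, 108, 141 and 140.

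Among the singly named genes that rose, Ssbp2, a single-stranded DNA-binding protein, went from 6.71 ± 6.13 to 174 ± 59.4 (log2 difference 3.09 ± 0.24, adjusted p = 0.000179). Ildr2 rose by 2.87 ± 0.15 on the log2 scale. Mtrex, the RNA helicase that serves the nuclear exosome, rose from a signal of 1.99 ± 1.94 to 119 ± 40.6, and Paip1, a partner of poly(A)-binding protein, rose by 2.45 ± 0.18 on the log2 scale. Gnb1, a G protein beta subunit, rose by 2.00 ± 0.19, and Acaa2, a mitochondrial thiolase of fatty acid oxidation, by 1.62 ± 0.11. Ssu72, a phosphatase of RNA polymerase, rose by 1.41 ± 0.16, Nlk, a serine/threonine kinase, by 1.35 ± 0.16, and Fstl5 by 1.27 ± 0.10. All of these had an adjusted p of 0.00369 or less. Here and below, each named value is that of 1 listed probe set. Other probe sets of the gene may be unnamed here, so the value may not describe the gene as a whole. Like Mtrex, the Gnb1 and Ssu72 probe sets were very dim in wildtype, at 6.29 and 9.25. The sizes for genes that were dim in wildtype were set by the pseudocount. From pseudocount 64 to pseudocount 1, Mtrex ran from 1.43 to 5.43, Ssbp2 from 1.73 to 5.07 and Ildr2 from 1.88 to 3.60. Gnb1 ran from 0.96 to 3.58, Ssu72 from 0.64 to 2.50 and Fstl5 from 0.82 to 1.55. Paip1, brighter in wildtype at 130, moved less, from 2.10 to 2.60. These rises have no fixed order. The Gnb1 and Ssu72 calls ended at pseudocount 1.

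Among the singly named genes that fell besides Evf2 and Lsm8, Galc, the lysosomal galactosylceramidase, went from 231 ± 12.6 to 31.6 ± 41.4 (log2 difference -2.74 ± 0.35, adjusted p = 0.00672). Dzip1, a protein of primary cilia, differed by -2.20 ± 0.31, Cuedc1 by -2.08 ± 0.23 and Prdx2, a peroxiredoxin that reduces hydrogen peroxide, by -2.04 ± 0.28. The pseudogene Pisd-ps3 (-1.91 ± 0.29), Chic1 (-1.65 ± 0.25), the transcriptional regulator Prdm16 (-1.64 ± 0.29) and the vesicle-tethering subunit Vps52 (-1.62 ± 0.14) also fell. So did Mapk8, a c-Jun N-terminal kinase (-1.59 ± 0.23), and Eme2, an endonuclease subunit (-1.56 ± 0.26). The table assigns related probe sets to Pisd-ps3 together with Pisd or Pisd-ps1, so the Pisd-ps3 value is uncertain. The sizes of these falls also moved with the pseudocount and have no fixed order: from pseudocount 64 to pseudocount 1, Galc ran from -1.74 to -3.57, Dzip1 from -1.15 to -3.61, Cuedc1 from -1.50 to -2.41, Chic1 from -0.96 to -2.22, Prdm16 from -0.86 to -2.67, Vps52 from -1.11 to -1.91, Mapk8 from -1.18 to -1.79 and Eme2 from -0.83 to -2.30. Prdx2 moved little, from -1.91 to -2.08. At pseudocount 1 all of these genes except Cuedc1 and Vps52 lost their calls, Pisd-ps3 included. Of the dimmer probe sets assigned to Pisd-ps3 alone, one differed by -2.33 (adjusted p = 0.0284) and another by -1.34 (adjusted p = 0.00975).

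The Prdm16 call ended without any 1 pool except mutant replicates 1 and 4, and the Eme2 call without any 1 pool except wildtype replicates 1 and 3 and mutant replicate 4. Chic1 lost it without wildtype replicate 4 or 5 or mutant replicate 1 or 2, Mapk8 without wildtype replicate 4 or mutant replicate 1 or 2, and Pisd-ps3 without wildtype replicate 5 or mutant replicate 1. Dzip1 and Prdx2 lost it without mutant replicate 1, while Galc, Cuedc1 and Vps52 were called without each pool in turn. Galc lost its call in 3 of 22 settings, among them pseudocount 1 (adjusted p = 0.0671), and Cuedc1 and Vps52 kept theirs in all.

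**Figure D2:**
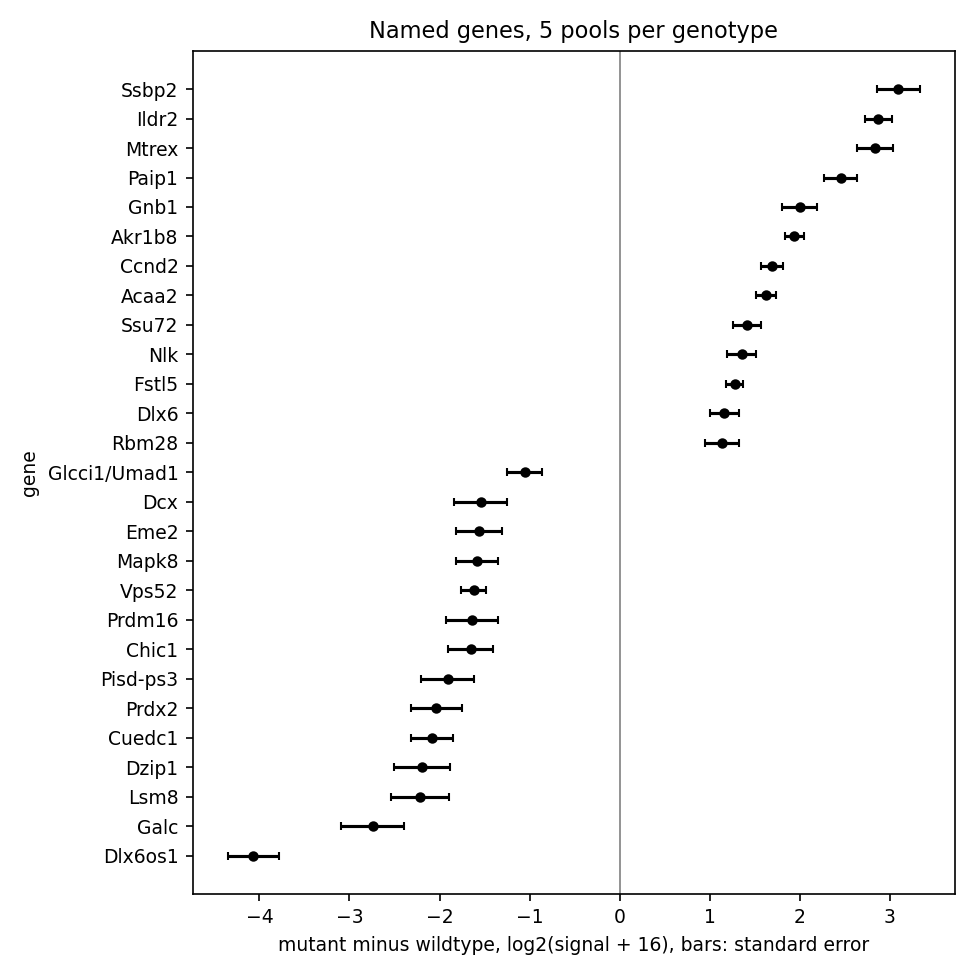
Mutant minus wildtype difference in log2(signal + 16) for the 27 named values, with standard errors, 5 pools per genotype. Values run from -4.07 for Dlx6os1 (Evf2) to 3.09 for Ssbp2.

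Of the fixed lists for cell state, the cell cycle list had 1 named member and the postmitotic neuron list 1. Ccnd2, a D-type cyclin that drives entry into the cell cycle, rose from 664 ± 89.7 to 2118 ± 292 (log2 difference 1.69 ± 0.12, adjusted p = 0.00011). Dcx, the microtubule protein of migrating young neurons, fell from 1027 ± 323 to 333 ± 148 (-1.54 ± 0.29, adjusted p = 0.0468), and its groups overlapped. The Dcx call ended in 14 of 22 settings, among them the omission of each pool except mutant replicate 4. The cell cycle list held 20 members and the postmitotic neuron list 16, and their other members had no named probe set. Names came only from the authors' deposited table, limited to a corrected p of at most 0.05 and at least 2-fold. Unless they are among its probe sets without a current symbol, the other members were not seen to pass that cut-off. Any probe sets of theirs were tested here without names, so neither value describes its list.

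The mutant pools were not alike. At 77 of the 96 listed probe sets mutant replicate 4 was the mutant pool nearest to wildtype. Its median position was 0.381 on a scale with 0 at the mean of the other mutant pools and 1 at the wildtype mean, while medians of the others lay between -0.117 and -0.0585. Galc read 106 there against 11.7 to 15.2 in the other mutant pools, and Prdx2 read 1032 against 300.3 to 379. On the same scale the chromosome 6 study genes lay at 0.158 (Akr1b8), 0.48 (Dlx6), 0.511 (Lsm8), 0.627 (Rbm28) and 0.658 (Glcci1/Umad1) in mutant replicate 4. Evf2 read 16.5 in this pool, inside the range of 9.47 to 58.1 of the others. Mutant replicate 5 stood apart on the first principal component (31.5% of variance), at a score of 51.0 against -11.0 to -0.00332 in the other pools, with 66 probe sets over 4-fold below every other array. The count of calls was 259 without mutant replicate 4 and 190 without mutant replicate 5.

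**Figure D3:**
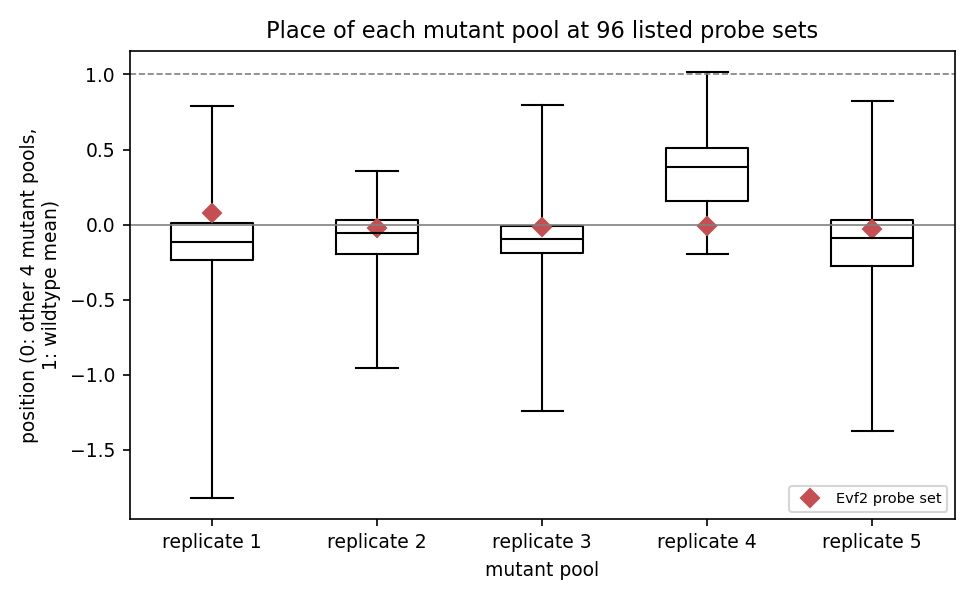
Position of each mutant pool at the 96 listed probe sets on linear signal, with 0 at the mean of the other 4 mutant pools and 1 at the wildtype mean; boxes span quartiles, lines mark medians, whiskers reach the extremes and diamonds mark Evf2. The median of replicate 4 was 0.381, while its Evf2 value was -0.0124.

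The authors' deposited table could be set beside this fit for its 96 probe sets, although it was made from the same arrays and is not independent. Of its 35 higher and 61 lower probe sets, 83 were called here (32 higher and 51 lower), and all 96 had the same direction and an unadjusted p under 0.05. A further 158 called probe sets were not in the authors' deposited table, 104 higher and 54 lower, among them 43 that differed at least 2-fold. Among them 1447360_at rose (2.00 ± 0.36) and 1437528_x_at fell (-2.42 ± 0.43), both unnamed here. The overlap dropped to 55 without wildtype replicate 4 and to 44 without mutant replicate 1.

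Listed probe sets lay on many chromosomes, but often near one another. Of 77 genes or unnamed probe sets with an alignment, 53 fell in 16 blocks, with neighbouring starts at most 5 Mb apart. This block count was not set against random draws, and the Pisd-ps3 block on chromosome 11 consists of overlapping alignments. Of the 82 listed probe sets with 1 alignment, 11 lay on chromosome 6, 7 higher and 4 lower, and all 11 were called. The Evf2 probe set was not among the 82, so the 11 leave it out. Besides the genes near Dlx6 the 11 included Ccnd2, 120.3 Mb from Dlx6, with A2m (-0.93 ± 0.15) and Vwf (0.89 ± 0.15) nearby. On chromosome 13, 4 listed genes lay within 0.0666 Mb, between 120217728 and 120284312: Paip1 (higher), the transcripts 4833420G17Rik (lower at each of 3 probe sets, adjusted p of 0.00752 or less) and 3110070M22Rik (-1.06 ± 0.16, adjusted p = 0.0159), and Tmem267 (-1.78 ± 0.39, adjusted p = 0.0895, not past the threshold). On chromosome 12, Galc and Trip11 (-1.10 ± 0.14, adjusted p = 0.00672) lay between 99440504 and 103097534. The largest block held 8 genes or unnamed probe sets on chromosome 4, Prdm16, Gnb1 and Ssu72 among them, 4 higher and 4 lower. A block of 5 on chromosome 17, between 34103775 and 36169627 and with Vps52 among them, was lower throughout.

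**Figure D4:**
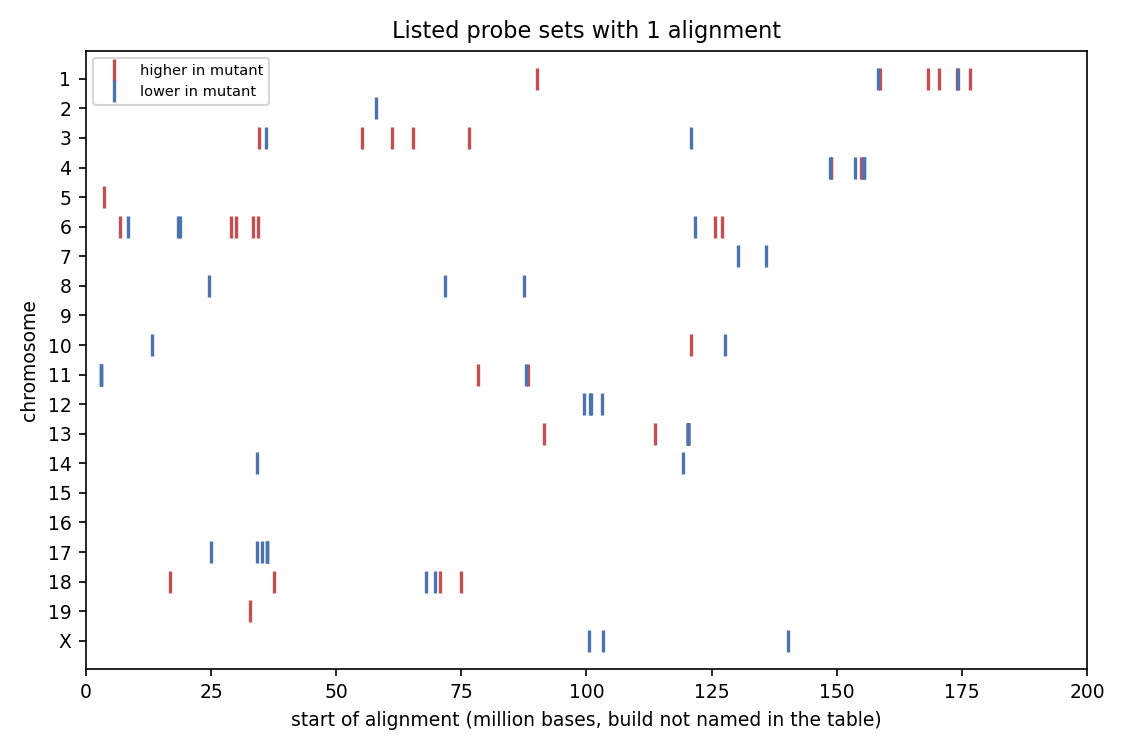
Start of each of the 82 listed probe sets with 1 alignment, in Mb of the build used by the deposited table, by chromosome; red marks are higher and blue marks lower in the mutant. Chromosome 6 carries 11 of them, 7 higher and 4 lower, and the Evf2 probe set is not among the 82.

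Males and females differed at 12 probe sets, all unnamed here, 9 higher in males and 3 in females. The probe set 1436936_s_at read 4301 ± 490 in females and 16.9 ± 5.97 in males (SD, n = 5 each; log2 difference male minus female -7.08 ± 0.14, limma adjusted p = 2.75e-10), and 1427263_at read 2017 ± 301 and 3.96 ± 3.11. In the other direction 1426438_at read 2.25 ± 3.24 in females and 332 ± 109 in males, and 1417210_at read 2.41 ± 2.24 and 252 ± 104. At all 12 the sexes were apart in every pool, as labelled. In mutant replicate 5, 4 of the 9 male-high probe sets lay over 1 log2 unit below the other males, and 5 lay within 0.5.

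The genotype effect, mutant minus wildtype, was compared between the sexes. Evf2 fell in females (-3.62 ± 0.37) and males (-4.51 ± 0.37), Dlx6 rose in both (1.18 ± 0.25 and 1.15 ± 0.25), and so did Ccnd2 (1.64 ± 0.18 and 1.75 ± 0.18). Galc differed by -3.16 ± 0.49 and -2.32 ± 0.49. In females 31 probe sets were called, 17 higher and 14 lower, and in males 28, 20 higher and 8 lower; 20 were called in both. The balance of directions was not stable: median-centred arrays gave 20 higher and 34 lower in females and 21 and 14 in males, an intensity trend gave 28 and 41 in females, and leaving out mutant replicate 4 gave 21 and 38 in females and 28 and 30 in males. All 31 had the same direction in males and all 28 in females. The difference of the effects was called by limma at 0 probe sets (1744 at an unadjusted p under 0.05, smallest adjusted p 0.999). Over the listed probe sets alone the smallest adjusted p of the difference was 0.782. The within-sex counts rest on 2 or 3 pools per group, and the female count fell to 3 without wildtype replicate 2 and the male count to 7 without mutant replicate 3 or 5.

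**Figure D5:**
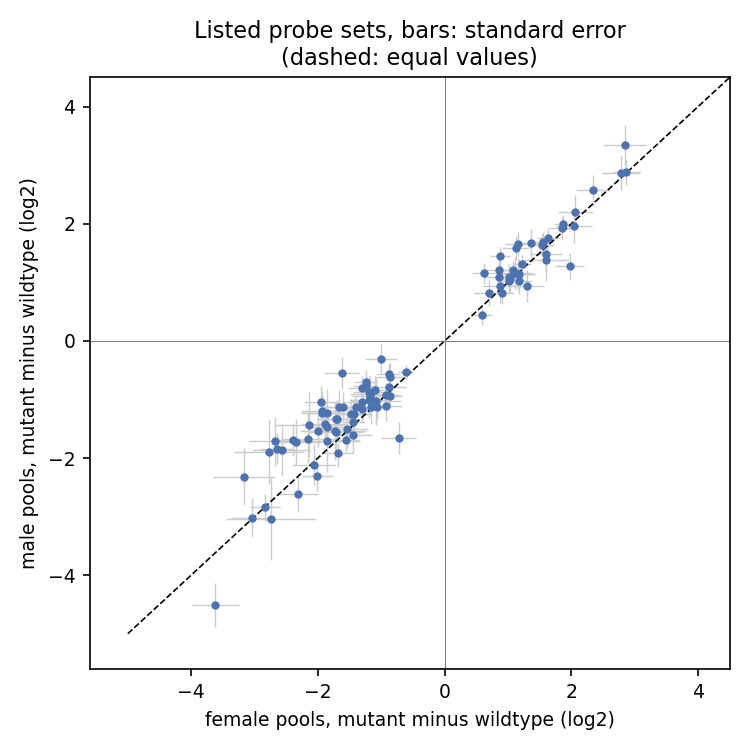
Mutant minus wildtype log2 difference in male pools against that in female pools for the 96 listed probe sets, with standard errors; the dashed line marks equal values. The probe sets had been chosen on these arrays for a genotype difference over both sexes, which nearly fixes a shared direction.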

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

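Apart from the tests of RNA quality and of outside tissue in mutant replicate 5 and the splits for the genotype count, the tests in this part were chosen after the result was seen. In 62 groups of 5 pools, 7 held a pool far from the other 4, where chance gives about 1 in 20.

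Dlx6os1 (Evf2) read 58.1 in mutant replicate 1, against 9.47 to 16.5 in the other mutant pools. Galc read 253 in wildtype replicate 3, against 223 to 228 in the other wildtype pools.

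Mutant replicate 4 held 4 of the 7 values: Paip1 at 490 (769 to 831 in the other mutant pools), Galc at 106 (11.7 to 15.2), Prdx2 at 1032 (300.3 to 379) and Eme2 at 42.4 (10.3 to 16.5). Each lay towards wildtype, as did the pool's median over probe sets called without it (0.404, against -0.0501 to 0.0478 for the other mutant pools). Wildtype tissue in the pool would bring Evf2 to about 246 signal units, but Evf2 read 16.5, at a position of -0.0124, which argues against such a mixture. A weaker contrast of the whole array would draw probe sets that differ between sexes together, but their median position was -0.0469, against 0.392 for listed probe sets on the same log2 scale. Background haplotypes that differ between mutant pools may account for the pattern, but positions within chromosomal blocks were not clearly more alike than by chance (permutation p = 0.23), so this stays open, as do other differences between the embryos of this pool.

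On the first principal component mutant replicate 5 scored 51.0, against -2.47 to -0.00332 in the other mutant pools. It had 297 probe sets over 2-fold below every other array (at most 3 on any other). It had 0 at least 4-fold above every other array, as did each of the others. The rule fixed beforehand would read this count as against tissue from outside the MGE. With 0 on every array the count cannot decide, so such tissue stays open. Female-high probe sets averaged 4.51 log2 units, inside the range of the other males (4.45 to 4.62) and far below females (at least 10.1), which argues against female tissue. The actin 3′ to 5′ ratio was 1.41 (1.257 to 1.381 elsewhere) and that of Gapdh 0.868 (0.822 to 0.862). Both lay above all other arrays, which the rule fixed beforehand reads as degraded RNA or 3′ bias. Each excess was less than 1 SD, a margin that rule did not include, so degraded RNA remains a candidate that is not settled. A defect that dimmed part of this array also stays open, since array images were not analysed here, so the low probe sets cannot be read as low transcripts; no biological explanation was tested, and the count of genotype calls was 190 without this pool.

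Other splits of the arrays did not reach either count of calls. Only 1 of 100 splits of the arrays into 5 and 5, the real one, gave as many as 241 for genotype, where the highest other split gave 1. For sex the real split was again 1 of 100, with 12 calls against at most 1. The other splits leave the real difference in the spread, which lowers their counts. They also cannot address differences of litter or background that go with genotype.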

How the results depend on the processing

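The settings of at least 2-fold and of the overlap and within-sex counts were chosen after seeing the data, except the overlap at an unadjusted p under 0.05. The genotype count of 241 became 375 with arrayWeights, 55 with pseudocount 1, 425 at adjusted p under 0.1, 604 at 1.5-fold with unadjusted p under 0.05, 117 with a 2-fold minimum, 78 by a plain t-test with Benjamini-Hochberg adjustment and 38 by that test with a 2-fold minimum; leaving out 1 pool gave 72 to 259. Pool numbers did not pair the samples (same-number correlations of deviations -0.129 to 0.0724, and no wildtype pool correlated best with its own number); with the replicate number as a block the count was 39 with the sex term and 139 without. The overlap of 83 became 34 with pseudocount 1, 29 with the replicate block and sex, 35 by the t-test and 44 to 93 without 1 pool. The female count of 31 became 54 with median-centred arrays, 69 with an intensity trend, 0 with pseudocount 1, 47 at adjusted p under 0.1 and 3 to 59 without 1 pool. The male count of 28 became 47 without dim probe sets, 46 with the trend, 53 with arrayWeights, 0 with pseudocount 1, 47 at adjusted p under 0.1 and 7 to 58 without 1 pool. The cause was not tested, and the within-sex ranges leave out omissions that left 1 pool in a group. The sex count stayed between 9 and 15, and the difference between sexes at 0 in all settings run, where leaving out a pool can leave 1 sample in a group, assumed to vary like the others. Of 27 named values none reversed over 22 settings; 11 kept their call throughout (Dlx6os1, Akr1b8, Ssbp2, Ildr2, Mtrex, Paip1, Ccnd2, Acaa2, Fstl5, Cuedc1, Vps52), and pseudocount 1, which spreads dim values, ended 15 calls. The replicate block with the sex term also ended 15 calls. The t-test ended 14: those of Dlx6, Lsm8, Rbm28, Glcci1/Umad1, Nlk, Galc, Dzip1, Prdx2, Pisd-ps3, Chic1, Prdm16, Mapk8, Eme2 and Dcx. Means over the probe sets of a gene, list tests and chromosome windows were not run, for want of names and positions.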

Other observations

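All tests of gene order were chosen after the result was seen, while the window around Dlx6 was set before. Other named genes of the deposited table, chosen after their values were seen, also changed. Sfrp1, a secreted protein that binds Wnt ligands, fell from 489 ± 72.1 to 170 ± 68.8 signal units (SD, 5 pools each; log2 difference -1.53 ± 0.21, adjusted p = 0.00922). C1qtnf12 fell from 145 ± 9.69 to 53.9 ± 16.1 (-1.24 ± 0.15), and the copper transporter Atp7a from 179 ± 20.9 to 80.9 ± 23.8 (-1.02 ± 0.18). Tiparp rose from 35.6 ± 8.98 to 91.9 ± 18.8 (1.14 ± 0.11), and the peroxisomal import factor Pex19 from 48.0 ± 4.02 to 118 ± 32.1 (1.06 ± 0.15).

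Listed genes lay near one another. Of 53 listed protein-coding genes placed in the RefSeq gene order of GRCm38.p6, 35 had another within 100 genes, against a median of 19 in 10000 random draws (permutation p = 2e-04). Regulation spreading along chromosome 6 from the Evf2 locus does not account for this alone, since without that chromosome 28 of 46 genes still had a neighbour, against a median of 16. Haplotype blocks of another strain carried with the mutant group are a candidate explanation (permutation p = 0.0011 without chromosome 6). With chromosome 6 included, 11 of 25 neighbouring pairs went in opposite directions. Shared regulation of neighbours was not tested, and the draws were not matched on expression. A variant flanking the Evf2TS allele cannot be told apart from an effect of Evf2 near the locus. Besides Dlx6, 1 listed probe set with 1 alignment, that of Glcci1/Umad1, lay within 10 Mb of Dlx6. The Evf2 probe set was not among those with 1 alignment, and 158 called probe sets have no position here. How far a linked segment runs was not measured. The same limit therefore holds for Lsm8 (11.99 Mb from Dlx6), Rbm28 (22.3 Mb) and Akr1b8 (27.5 Mb), beyond the window.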
